A study of Mus musculus with 11 samples.

How the data were processed

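Ovarian granulosa cells, the somatic cells that surround the oocyte in a follicle, were taken from C57BL/6 mice that were untreated (0 h) or had received equine chorionic gonadotropin (eCG) 48 h earlier. eCG is a hormone with follicle-stimulating hormone (FSH) activity in mice, and the labels describe the treatment as FSH. Its FSH activity and any activity of luteinizing hormone cannot be told apart here. RNA was sequenced from 3 libraries per group, labelled as postnatal day 21, and H3K4me3, a histone mark of active promoters, was measured by chromatin immunoprecipitation (ChIP-seq) in 2 libraries per group. The series has 11 samples, of which 1 is an input DNA library that was not used here. The series describes the libraries of a group as biological replicates.

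Both deposited tables hold raw counts per Entrez gene ID, with no normalization by the authors that the values show: whole numbers whose totals differ between libraries. Per the submitters' processing notes, the RNA data involved FastQC 0.11.5, Picard, STAR, kallisto and sleuth, and the ChIP-seq data involved Trimmomatic, Bowtie2 2.2.9, MACS2 2.2 and ChIPseeker 1.18.0, with genome build mm10 in both. The notes used here give no role or order of these tools, so the program that made the deposited counts, whether strand was used, and the window counted for each gene in the H3K4me3 table are not given in the sources used here. Because the window is not given, an H3K4me3 value is called the H3K4me3 count of a gene and not of a promoter. RNA columns carry the name of their sample. The H3K4me3 columns could be tied to a group by their names, and the number that ends each column name was used only to name a library, to leave libraries out and to form blocks.

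Symbols and coordinates came from a gene table of GRCm38.p6, the assembly that mm10 stands for, and give whole genes without exons or strand. A symbol was found for 24742 of 24809 gene IDs in the RNA table and for 24472 of 24541 in the H3K4me3 table. RNA counts were 0 in all libraries for 5243 IDs. Overlapping genes were looked up in the table because reads from overlapping genes may not be told apart, and H3K4me3 neighbours were defined as genes within 5000 bp with counts within 20%. In H3K4me3, 986 IDs had counts identical to another ID in every library.

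Total counts were 12013849 to 26343971 per RNA library and 11989769 to 17968033 per H3K4me3 library. The biological coefficient of variation was 0.141 for RNA and 0.0465 for H3K4me3. Replicates were compared by a chi-square statistic over genes, which was 5.41 to 40.8 per degree of freedom between RNA libraries of a group and 1.69 and 4.00 between H3K4me3 libraries, so no pair was within sampling noise and each library was counted once.

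Groups, tests, gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. Within each assay, 48 h was compared with 0 h by edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on the deposited counts, with TMM scaling, the filterByExpr filter and Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05 with no fold minimum. Log2 fold changes are 48 h over 0 h with a standard error (SE) derived from the test statistic. The SE and the p-values use variation shared across genes. They can be smaller than the spread of a gene's own libraries would give, above all in H3K4me3. Normalised read counts (CPM, computed here with TMM scaling) are given as mean ± SD over the libraries of a group. Calls in both assays were compared by a two-sided Fisher's exact test and a Spearman correlation across genes, which are not independent replicates.

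The 25 gene lists, 8 of them markers of cell types or states, held 438 genes, of which 437 matched the gene table. They covered steroidogenesis, FSH response and hormone receptors, cholesterol biosynthesis and uptake, cell cycle, growing-follicle granulosa markers, the ovulatory response, Hippo targets, Wnt components, apoptosis, glycolysis, extracellular matrix, angiogenic factors, H3K4 methylation machinery, immediate early genes, AP1 and cAMP targets, oxidative phosphorylation, gap junction and oocyte dialogue, and markers of theca, oocyte, endothelium, immune cells, smooth muscle, surface epithelium, red blood cells and luteal cells. Each list was tested with camera (limma 3.58.1) at a preset correlation of 0.01 and again with an estimated correlation, and with fry. With an estimated correlation, camera takes its degrees of freedom from the few libraries. A list can then fail there without strong correlation among its genes. Camera compares a list with the other genes, and its adjusted p is over the 25 lists. Fry tests whether the genes of a list move, on balance, 1 way. Member counts are given at an adjusted p over all genes tested and adjusted over the list alone.

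Named genes were, in RNA, the 10 largest rises and 10 largest falls among called genes with a mean of at least 5 CPM and groups that did not overlap, and in H3K4me3 the 8 largest of each with a mean above the median gene; predicted genes were passed over. In addition 8 genes were always named (Fshr, Lhcgr, Cyp19a1, Cyp11a1, Star, Inhba, Ccnd2 and Amh), with up to 4 members of a list by smallest p, and the 5 genes per direction called in both assays with the largest summed change. Other list members are named as examples after their values were seen. Some genes that these rules select are not reported here.

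The alternatives were other scalings (DESeq2 size factors, library size only), no filter, DESeq2 1.42.0, limma-voom, a log2 fold minimum of 1, a threshold of 0.01, the replicate number as a block, and each library left out in turn. Alternatives chosen after seeing the data were a crossed block, IDs with identical counts kept once, and only gene windows above background in H3K4me3. Background was set at 3 times the median of 5129 genes with no RNA count, which was 1.57 CPM, giving a limit of 4.71 CPM. The scalings were also applied to the list tests after seeing the data. The tests were tested on simulated counts, in which 100 genes changed by each log2 fold, equally often up and down. Genes varied independently there, and no effect common to a whole library was added. The changed genes were drawn from those with at least 5 CPM, so recovery at lower counts was not tested. For RNA, over 14235 genes, edgeR recovered 86% of genes changed by a log2 fold of 1 and 100% of those changed by 2. Of the genes it called 8.37% were unchanged ones, and with DESeq2 on the same counts 19.1%, both above the 5% that the threshold allows. For H3K4me3, over 24469 genes, edgeR recovered 91% at a log2 fold of 0.5 and 99% at 1, and 5% of its calls were false. These shares need not hold for the real data, where many more genes were called (4585 in RNA) and single libraries moved the counts.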

Results

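Granulosa cells of immature mice were compared before and 48 h after eCG, the gonadotropin used to start follicle growth, by RNA sequencing (3 libraries at 0 h and 3 at 48 h) and by ChIP-seq of H3K4me3 (2 and 2). An age is labelled for the RNA libraries only. The series has no untreated group at 48 h, so effects of eCG cannot be told apart from those of time or of collection. The series joins both assays to find genes that respond to FSH, but no group received FSH itself. Total RNA counts were 15050013, 18511429 and 17984380 in 0 h replicates 1 to 3 and 14150715, 26343971 and 12013849 in 48 h replicates 1 to 3. The 10 most abundant genes took 4.26% to 4.89% of the counts at 0 h and 7.28% to 7.54% at 48 h. Total H3K4me3 counts were 15124233 and 11989769 at 0 h and 17137463 and 17968033 at 48 h.

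The RNA comparison asked which transcripts differed after 48 h of eCG. Lhcgr (gene ID 16867; chromosome 17, 88716384 to 88792059), the receptor for luteinizing hormone, rose from 66.7 ± 23.2 to 884 ± 245 CPM (mean ± SD, n = 3 per group), a log2 fold change of 3.73 ± 0.30 (SE) with an adjusted p of 1.79e-04 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Fshr (gene ID 14309; chromosome 17, 88984952 to 89200675), the FSH receptor, rose from 106 ± 20.6 to 264 ± 25.2 CPM (log2 1.32 ± 0.14, adjusted p = 5.26e-04). Amh (gene ID 11705; chromosome 10, 80805240 to 80807679), anti-Müllerian hormone of small growing follicles, fell from 901 ± 201 to 346 ± 194 CPM (log2 -1.38 ± 0.34, adjusted p = 0.0158). The call of Amh was lost without 0 h replicate 1 (0.0527), 48 h replicate 2 (0.0621) or 48 h replicate 3 (0.0671), and over all alternatives its adjusted p was 2.96e-04 to 0.0671.

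Of 25 genes of the FSH response and hormone receptors, 16 rose, 2 fell and 7 did not pass the test. The largest rise in the list was that of Sfrp4 (gene ID 20379; chromosome 13, 19623175 to 19632825), a secreted Wnt antagonist, from 10.6 ± 4.61 to 1084 ± 336 CPM (log2 6.68 ± 0.40). Pappa, a protease of insulin-like growth factor binding proteins, rose by a log2 fold of 4.14, and Comp, a matrix protein, by 4.65. Inhba, the activin and inhibin subunit, rose from 3322 ± 672 to 10962 ± 795 CPM (log2 1.72 ± 0.17, adjusted p = 3.38e-04). Adjusted over the list alone, 16 rose and 4 fell. The list stood above other genes by camera (adjusted p = 1.21e-13), a call lost with an estimated correlation (adjusted p = 0.0740 with an estimated correlation).

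Steroid synthesis and its cholesterol supply were higher together. Cyp19a1 (gene ID 13075; chromosome 9, 54165937 to 54268164), the aromatase that makes oestradiol, rose from 210 ± 64.8 to 826 ± 98.5 CPM (log2 1.98 ± 0.22). Cyp11a1, the side-chain cleavage enzyme, rose from 841 ± 221 to 3224 ± 1041 CPM (log2 1.94 ± 0.26), and Star, which brings cholesterol into mitochondria, rose from 38.2 ± 21.3 to 241 ± 147 CPM (log2 2.66 ± 0.50). Adjusted p-values of these 3 genes were 6.29e-04, 0.00120 and 0.00502. Of 18 steroidogenesis genes 14 rose, 1 fell and 3 did not pass (15 and 1 adjusted over the list alone), with camera at 9.63e-10 and an adjusted p = 0.171 with an estimated correlation. All 23 genes of cholesterol biosynthesis and uptake rose, also when adjusted over the list alone, with a median log2 fold of 1.50. Examples were Nsdhl at 1.26 and Fdft1, which makes squalene, at 1.50, although Fdft1 overlaps Ctsb. Camera gave this list 1.14e-33, with an adjusted p = 0.171 with an estimated correlation.

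Luteal markers were higher as well, with 9 of 11 rising, 0 falling and 2 not passing (9 and 1 adjusted over the list alone). The prolactin receptor Prlr rose by 2.64 and the prostaglandin receptor Ptgfr by 4.54 on the log2 scale; 7 of the 11 genes also stand in another list. The camera adjusted p was 1.65e-10, and the adjusted p = 0.217 with an estimated correlation. Of 20 ovulatory response genes 10 rose, 2 fell and 8 did not pass (11 and 2 adjusted over the list alone). Adamts1, a protease, rose by 2.16, Vcan, a matrix proteoglycan, by 2.13 and the transcription factor Runx2, which overlaps Supt3, by 4.15, whereas Runx1 fell by 0.98. The camera adjusted p of this list was 2.85e-07, lost with an estimated correlation (adjusted p = 0.171 with an estimated correlation).

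Glycolysis genes rose in 14 of 20 cases, fell in 1 and did not pass in 5 (15 and 1 adjusted over the list alone). The lactate transporter Slc16a3, which overlaps Csnk1d, rose by 2.17, the glucose transporter Slc2a1 by 1.02 and Pkm by 0.94 on the log2 scale. Camera gave 1.25e-08, with an adjusted p = 0.237 with an estimated correlation. For oxidative phosphorylation 9 of 20 rose, 0 fell and 11 did not pass (12 and 0 adjusted over the list alone), among them Sdhb (0.51) and Cycs (0.56). That list had a camera adjusted p of 7.11e-04 and an adjusted p = 0.639 with an estimated correlation.

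Cell cycle genes had a median log2 fold of 0.32. Of 30, 8 rose, 0 fell and 22 did not pass (5 and 0 adjusted over the list alone), with the replication factor Mcm3 at 0.68 and the ribonucleotide reductase subunit Rrm2 at 0.57. Relative to the 0 h mean, the list median was 0.05 in 48 h replicate 1 and 0.45 and 0.38 in 48 h replicates 2 and 3, with 0.13 in 0 h replicate 1. Camera gave an adjusted p of 0.00253, and the adjusted p = 0.722 with an estimated correlation. The cyclin Ccnd2 did not pass, at 426 ± 25.3 and 551 ± 90.4 CPM (log2 0.37 ± 0.13, adjusted p = 0.0606). It passed with DESeq2 size factors (0.0466), with DESeq2 (0.00910) and without 48 h replicate 1 (0.00273), and over all alternatives its adjusted p was 0.00273 to 0.258.

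Matrix genes rose in 14 of 26 cases, fell in 2 and did not pass in 10 (18 and 2 adjusted over the list alone). Vcan and Comp belong to this list too, and the matrix protease gene Mmp11 fell by 1.21. Camera gave 1.23e-08 and an adjusted p = 0.443 with an estimated correlation. Relative to the 0 h mean, the median of the matrix list was 1.45 in 48 h replicate 1 and 0.34 and 0.47 in 48 h replicates 2 and 3, and the median of the endothelial markers was 2.50, 0.85 and 1.13. For gap junction and oocyte dialogue genes 5 of 15 rose, 2 fell and 8 did not pass (8 and 2 adjusted over the list alone). Nppc, the peptide that holds oocytes in meiotic arrest, rose by 1.55 and Gja1, a connexin, by 0.81. The camera adjusted p of 0.0188 became 0.138 without 48 h replicate 1, and the call was also lost with the replicate number as a block. Over all alternatives the adjusted p ranged from 0.00922 to the adjusted p = 0.423 with an estimated correlation.

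Among lists with lower members, 8 of 20 genes of the H3K4 methylation machinery fell, 0 rose and 12 did not pass (10 fell adjusted over the list alone). The methyltransferase genes Setd1b and Kmt2a fell by 0.49 and 0.40. For this list camera gave 0.0125, 0.0741 without 48 h replicate 1, and from 0.00498 up to the adjusted p = 0.501 with an estimated correlation over all alternatives. Growing-follicle markers moved both ways, with 5 of 21 rising, 9 falling and 7 not passing (5 and 10 adjusted over the list alone). Their median relative to 0 h was -0.03 in 48 h replicate 1 and -0.44 and -0.38 in 48 h replicates 2 and 3. Nr0b1, a repressor of steroidogenic genes, fell by 1.50 and the transcription factor Wt1 fell by 1.07, while Wnt4 rose by 1.28. This list did not pass camera (0.275), but did so without 0 h replicate 2 (0.0161) and with the replicate number as a block, within a range of 0.0161 to 0.722.

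Immediate early genes included Nr4a1, an orphan receptor induced by many stimuli, which fell from 108 ± 63.8 to 24.8 ± 2.35 CPM (log2 -2.12 ± 0.43, adjusted p = 0.00673), Egr1, which fell by 1.55, and the phosphatase gene Dusp1, which rose by 2.34. In all 1 of 18 rose, 7 fell and 10 did not pass, with the same counts adjusted over the list alone. Camera gave 0.0628 for this list and 5.81e-04 without 0 h replicate 2, and its range was 5.81e-04 to 0.443.

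Signalling lists showed members moving in both directions and did not pass camera. Wnt components rose in 7 of 21 cases, fell in 6 and did not pass in 8 (8 and 7 adjusted over the list alone; camera 0.649), with Tcf7l2 falling by 0.89; their median was -0.07 and their mean 0.18. Hippo targets rose in 2 of 16 cases, fell in 3 and did not pass in 11 (3 and 4 adjusted over the list alone; camera 0.736), with Dock5 rising by 2.10; median and mean were -0.07 and -0.05 although the test pointed up. Of 16 angiogenic factors 4 rose, such as Angpt1 at 1.77, 4 fell, such as Edn1 at -1.39, and 8 did not pass (4 and 4 adjusted over the list alone; camera 0.805), with a median of -0.05 and a mean of 0.12. AP1 and cAMP targets had 3 rises and 3 falls among 16, with 10 not passing (3 and 3 adjusted over the list alone; camera 0.815), among them the phosphodiesterases Pde4b at 2.03 and Pde7b at -1.30. Apoptosis genes had 2 rises and 4 falls among 19, with 13 not passing (2 and 4 adjusted over the list alone; camera 0.805), including the proapoptotic Bcl2l11 at -0.47.

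Markers of other cell types did not move alike. Endothelial markers rose in 10 of 12 cases, fell in 0 and did not pass in 2 (11 and 0 adjusted over the list alone), for example Cdh5 by 1.84 and Egfl7 by 1.43, with camera at 1.91e-04 and an adjusted p = 0.587 with an estimated correlation. The 3 measured red-cell genes, among them Slc4a1 and Alas2 (which overlaps Apex2), rose, by 2.69 in the median, and all 3 also adjusted over the list alone. Camera gave 0.0120 for them, 0.0816 without 48 h replicate 1 and, across alternatives, 2.59e-10 to the adjusted p = 0.443 with an estimated correlation. Relative to the 0 h mean, the red-cell median was 3.09, 0.79 and 3.10 in 48 h replicates 1 to 3, with 0.48 in 0 h replicate 3. Oocyte markers fell in 7 of 18 cases, rose in 0 and did not pass in 11, the same adjusted over the list alone, with Tcl1 at -2.05, a camera adjusted p of 5.12e-04 and an adjusted p = 0.639 with an estimated correlation. Their median relative to 0 h was -0.18 in 48 h replicate 1 and -1.60 and -1.63 in 48 h replicates 2 and 3.

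None of the other marker lists passed camera. Of 14 theca markers 2 rose, 3 fell and 9 did not pass (2 and 3 adjusted over the list alone; camera 0.832), with the median at 0.19 and the mean at 0.05 although the test pointed down. None of 14 immune markers passed, also adjusted over the list alone (camera 0.649). For smooth muscle and pericytes 2 of 10 rose, 0 fell and 8 did not pass (2 and 0 adjusted over the list alone; camera 0.721). Relative to 0 h, the medians in 48 h replicates 1 to 3 were 0.91, -0.33 and -0.16 for this list and 0.63, -0.29 and -0.22 for theca markers. For surface epithelium 0 of 10 rose, 1 fell (Krt8, by 0.44) and 9 did not pass (0 and 1 adjusted over the list alone; camera 0.721).

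Outside the lists, the largest rises were those of Atp12a and Pik3c2g, each with 2 counts over the 0 h libraries. With 554 and 550 counts at 48 h, the depth-corrected ratios were 306 (95% interval 84.4 to 2535) and 304 (83.8 to 2516), intervals that cover counting error only. Other large rises were those of the cadherin Cdh15 (log2 7.20 ± 0.68), the drug transporter Abcb1b (5.84 ± 0.58), the Wnt ligand Wnt10b (5.68 ± 0.27), Elapor1 (5.13 ± 0.66), the adrenergic receptor Adra1d (4.75 ± 0.55) and Cemip, which degrades hyaluronan (4.72 ± 0.22). The largest falls were those of Ngef (gene ID 53972; chromosome 1, 87476829 to 87573870; log2 -2.38 ± 0.18), Dact1 (-2.19 ± 0.20, overlapping a predicted gene), Nr4a1, Nlrp10 (-2.09 ± 0.19), Atoh8 (-2.08 ± 0.18), the nitric oxide synthase Nos2 (-2.01 ± 0.14), the imprinted RNA H19 (-1.98 ± 0.31), Sez6 (-1.95 ± 0.23), Pdzd7 (-1.94 ± 0.21, overlapping Lzts2 and Sfxn3) and Gulo (-1.93 ± 0.23). Their adjusted p-values were between 2.20e-05 for Wnt10b and Cemip and 0.00673 for Nr4a1.

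In all 4585 of 14401 genes tested were called in RNA, 2303 higher and 2282 lower at 48 h, and 6894 genes had groups that did not overlap, which chance gives for 10% of genes with 3 against 3. With library size as the only scaling, the share of calls that were higher was 26.8% in place of 50.2%, and the median of all genes lay at -0.20 in place of -0.03. The count was 2956 without 0 h replicate 2 and 2882 without 0 h replicate 3, and lower calls numbered 1295 and 1228 without 48 h replicates 2 and 3.

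**Figure D1:**
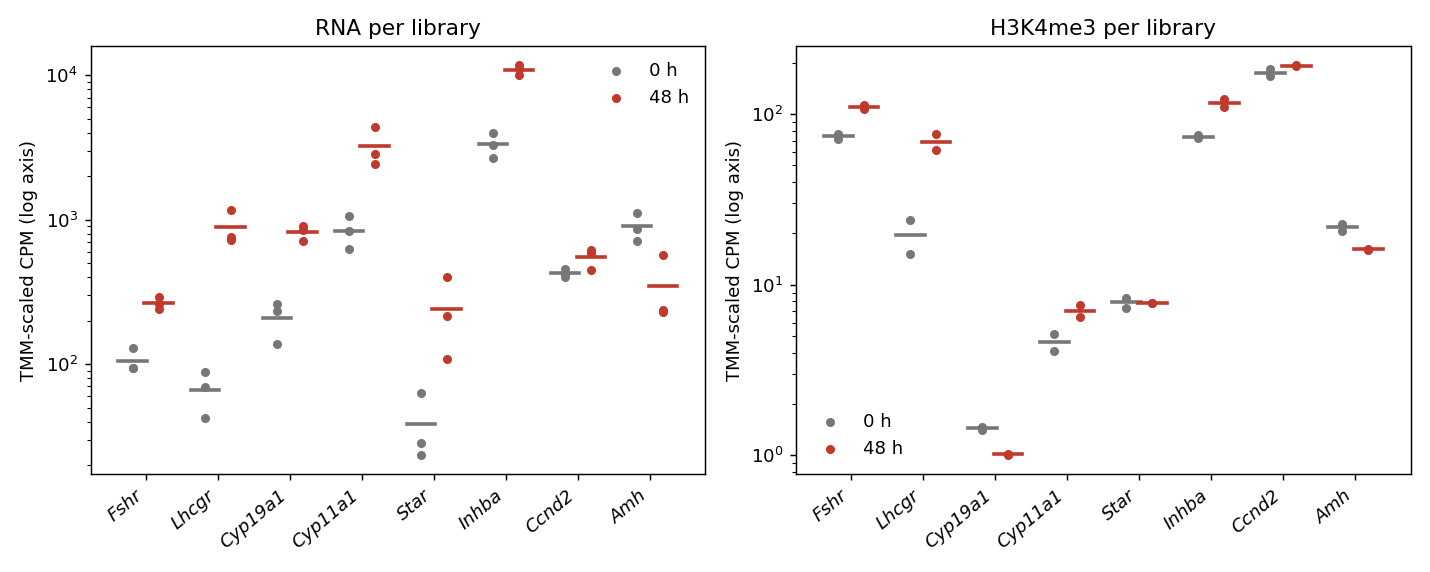
Normalised counts (TMM-scaled CPM, log axis) of 8 genes named in advance in each RNA library (left) and each H3K4me3 library (right), with grey points at 0 h, red points at 48 h and a line at each group mean. Lhcgr RNA went from a mean of 66.7 to 884 CPM and its H3K4me3 from 19.6 to 69.0 CPM, whereas the H3K4me3 means of Star were 7.88 and 7.86 CPM.

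The H3K4me3 comparison asked where the mark at genes differed after eCG. The largest rise among the named genes was at Lhcgr, from 19.6 ± 6.16 to 69.0 ± 10.3 CPM (mean ± SD, n = 2 per group), a log2 fold of 1.79 ± 0.11 with an adjusted p of 3.66e-17 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. With n = 2, the SE and p rest on variation shared across genes and do not measure the spread of this gene's own libraries. H3K4me3 rose at Fshr from 74.0 ± 3.23 to 109.5 ± 4.27 CPM (log2 0.56 ± 0.07, adjusted p = 1.08e-07) and at Inhba from 73.5 ± 2.09 to 116 ± 9.08 CPM (log2 0.66 ± 0.07, adjusted p = 4.46e-09). It fell at Amh from 21.7 ± 1.29 to 16.2 ± 0.140 CPM (log2 -0.42 ± 0.11, adjusted p = 0.0114). The call at Amh was lost with DESeq2 (0.0889) and without 0 h replicate 1 (0.207) or 2 (0.166), in a range of 4.20e-04 to 0.207.

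The counted windows of 4 further genes named in advance did not pass without a block. Cyp19a1 had 1.44 ± 0.0410 and 1.02 ± 0.00682 CPM (log2 -0.51 ± 0.38, adjusted p = 0.491), which lay below the background limit of 4.71 CPM set from genes with no RNA count. Cyp11a1 had 4.59 ± 0.738 and 7.06 ± 0.816 CPM (log2 0.61 ± 0.21, adjusted p = 0.0621), Star 7.88 ± 0.735 and 7.86 ± 0.00115 CPM (log2 0.00 ± 0.18, adjusted p = 0.993) and Ccnd2, which has a predicted neighbour of like count, 175 ± 11.8 and 192 ± 0.897 CPM (log2 0.14 ± 0.07, adjusted p = 0.234). With the crossed block, chosen after seeing the data, Cyp11a1 (0.00345) and Ccnd2 (0.0152) passed, the lowest values of ranges that reached 0.331 and 0.885 over all alternatives.

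Other large rises of H3K4me3 were at Grem1, a bone morphogenetic protein antagonist (gene ID 23892; chromosome 2, 113748675 to 113758648; log2 1.09 ± 0.08), Mro (1.07 ± 0.09), Rnf220 (1.03 ± 0.13), Pdlim2 (1.02 ± 0.11, with a predicted neighbour of like count), the adiponectin receptor Adipor2 (0.996 ± 0.11) and the corepressor Tle2 (0.99 ± 0.09). Large falls were at Nrip2 (-1.23 ± 0.12), Nupr1 (-0.997 ± 0.11), B3galt2 (-0.97 ± 0.10), the chemokine receptor Ackr3 (-0.93 ± 0.08), the neighbours Wfdc10 and Wfdc9 (-0.91 ± 0.10 and -0.90 ± 0.10, with like counts) and Slc18a2 (-0.88 ± 0.08).

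Of 25 FSH response and receptor genes H3K4me3 rose at 14, fell at 3 and did not pass at 8 (15 and 3 adjusted over the list alone), including Comp at 1.45, Prlr at 0.78 and Inhbb at 0.71. The camera adjusted p was 1.17e-20, and the adjusted p = 0.230 with an estimated correlation. That estimate, 0.0131, was near the preset 0.01, so correlation among the genes does not account for this loss. Among 11 luteal markers it rose at 5, fell at 1 and did not pass at 5 (6 and 1 adjusted over the list alone), with Ptgfr at 0.90 and Hsd3b1, which makes progesterone, at 0.63, a camera adjusted p of 5.40e-15 and an adjusted p = 0.305 with an estimated correlation. Steroidogenesis genes gained the mark at 7 of 19, lost it at 1 and did not pass at 11 (8 and 1 adjusted over the list alone). Nr5a1, the regulator of steroidogenic genes, rose by 0.60 and Hsd17b1 by 0.40, with camera at 4.42e-05 and an adjusted p = 0.311 with an estimated correlation.

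Cholesterol genes gained H3K4me3 at 12 of 23, lost it at 0 and did not pass at 11 (15 and 0 adjusted over the list alone), for example Fdps at 0.49 and Msmo1 at 0.47. Camera gave 1.99e-13, and the adjusted p = 0.230 with an estimated correlation. At glycolysis genes the mark rose at 8 of 21, fell at 1 and did not pass at 12 (12 and 1 adjusted over the list alone), with Slc16a3 at 0.87 and Gapdh, whose neighbour Ncapd2 had a like count, at 0.44. Camera gave 1.13e-06, and the adjusted p = 0.230 with an estimated correlation. Cell cycle genes rose at 5 of 30, fell at 0 and did not pass at 25 (5 and 1 adjusted over the list alone), with camera at 0.0169. That call was lost with library size only (0.0912) and without 0 h replicate 1 (0.133) or 48 h replicate 2 (0.133), in a range from 0.00546 up to the adjusted p = 0.452 with an estimated correlation.

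H3K4me3 was lower at growing-follicle markers, falling at 7 of 21, rising at 3 and not passing at 11 (10 fell and 3 rose adjusted over the list alone). It fell by 0.88 at Slc18a2, by 0.65 at Wt1, which has an antisense neighbour of like count, and by 0.64 at Kctd14, and rose by 0.61 at Id1. The camera adjusted p was 4.12e-06, with an adjusted p = 0.230 with an estimated correlation. Surface epithelium markers lost the mark at 4 of 10, gained it at 0 and did not pass at 6 (5 fell and 1 rose adjusted over the list alone), with the keratin gene Krt8 at -0.35, camera at 6.10e-04 and an adjusted p = 0.452 with an estimated correlation. Without 0 h replicate 1, Krt8 had an adjusted p of 0.352, in a range of 9.67e-05 to 0.352.

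The remaining lists did not pass camera in H3K4me3. Genes of the H3K4 methylation machinery rose at 3 of 20 and fell at 0 (5 and 0 adjusted over the list alone; camera 0.0503), and passed without 0 h replicate 2 (0.0154) or 48 h replicate 2 (0.00890), in a range of 0.00890 to 0.611. Ovulatory genes rose at 8 of 23 and fell at 1, Rgs2 at -0.46 (9 and 2 adjusted over the list alone; camera 0.103), and passed without 0 h replicate 1 (0.0207) or 48 h replicate 1 (0.0119), in a range of 0.0119 to 0.611. Wnt components rose at 4 of 22 and fell at 1 (5 and 1 adjusted over the list alone; camera 0.103). Theca markers rose at 1 of 14 and fell at 2 (1 and 3 adjusted over the list alone; camera 0.103, and 0.0220 without 48 h replicate 2, in a range of 0.0220 to 0.611). Angiogenic factors rose at 4 of 18 and fell at 5, among them Thbs1 at -0.55 (4 and 5 adjusted over the list alone; camera 0.159). Matrix genes rose at 5 of 26 and fell at 3 (5 and 4 adjusted over the list alone; camera 0.201, and 0.0460 without 48 h replicate 1, in a range of 0.0460 to 0.591).

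Oxidative phosphorylation genes rose at 1 of 20 and fell at 0 (1 and 0 adjusted over the list alone; camera 0.201, and 0.0239 without 0 h replicate 2, in a range of 0.0239 to 0.887). Gap junction genes rose at 2 of 15, including Nppc at 0.55, and fell at 2 (3 and 2 adjusted over the list alone; camera 0.299). Apoptosis genes rose at 1 of 21, Bcl2l1 at 0.42 (1 and 0 adjusted over the list alone; camera 0.379). AP1 and cAMP targets rose at 4 of 16 and fell at 2 (4 and 2 adjusted over the list alone; camera 0.514), with the median at 0.02, the mean at -0.05 and the test pointing down. Immediate early genes rose at 4 of 18 and fell at 2, among them Nr4a1 at -0.65 (5 and 2 adjusted over the list alone; camera 0.847). Hippo targets rose at 3 of 17 and fell at 3 (3 and 3 adjusted over the list alone; camera 0.959).

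Among the marker lists, H3K4me3 passed at 0 of 21 oocyte markers (0 adjusted over the list alone; camera 0.299) and at 0 of 7 red-cell genes (0 adjusted over the list alone; camera 0.565). Immune markers rose at 1 of 15 (1 adjusted over the list alone; camera 0.801) and smooth muscle markers fell at 1 of 10 (1 adjusted over the list alone; camera 0.361). Endothelial markers fell at 1 of 12 (1 adjusted over the list alone; camera 0.857), with the median and the mean at 0.03 although the test pointed down. Windows at or below the background limit of 4.71 CPM were 17 of 21 for oocyte, 6 of 7 for red-cell, 13 of 15 for immune, 5 of 10 for smooth muscle and 8 of 12 for endothelial markers.

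In all 2062 of 24476 genes were called in H3K4me3, 1554 higher and 508 lower at 48 h. The share of higher calls was 75.4%, against 52.3% with library size as the only scaling (945 higher and 862 lower) and 55.3% of 2012 calls when only 14793 windows above background were tested (1112 and 900). In the same order, the median log2 fold of windows above background was 0.052, -0.002 and 0.003. The excess of higher calls therefore depends on the scaling. The count was 282 without 0 h replicate 1, 1252 without 0 h replicate 2 and 1181 without 48 h replicate 1, and DESeq2 called 865.

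**Figure D2:**
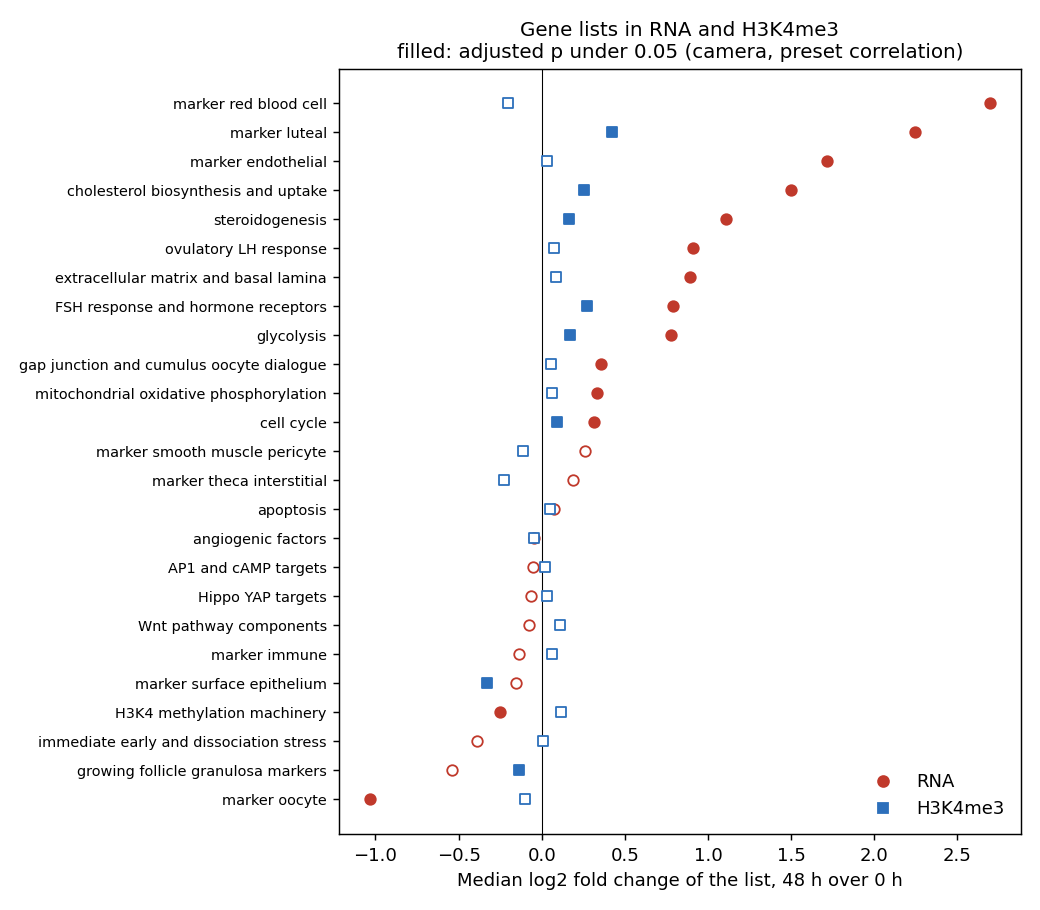
Median log2 fold change (48 h over 0 h) of each of the 25 gene lists in RNA (red circles) and H3K4me3 (blue squares), with filled symbols for lists whose camera adjusted p, at the preset correlation, was under 0.05. Cholesterol genes had medians of 1.50 in RNA and 0.26 in H3K4me3, and endothelial markers 1.72 and 0.03.

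Both assays were then joined to ask whether genes that changed in RNA also changed in H3K4me3. Among genes called higher in both, Sfrp4 changed by log2 6.68 in RNA and 0.72 in H3K4me3, Wnt10b by 5.68 and 0.89, Abcb1b by 5.84 and 0.35, Comp by 4.65 and 1.45, and the lipid droplet protein gene Plin4 by 4.71 and 1.14, although the window of Plin4, at 1.80 ± 0.0773 and 3.99 ± 0.721 CPM, lay below the background limit of 4.71 CPM. Among genes called lower in both, Nlrp10 changed by -2.09 and -1.03, Gulo by -1.93 and -1.10, Atoh8 by -2.08 and -0.87, Nrip2 by -1.68 and -1.23, and Otof, whose neighbour Fam166c had a like count, by -1.90 and -0.98. The H3K4me3 mean of Wnt10b at 0 h (4.38 CPM) and that of Otof at 48 h (3.18 CPM) also lay under the background limit. Without H3K4me3 0 h replicate 1, the H3K4me3 adjusted p was 0.395 at Wnt10b, 0.381 at Abcb1b, 0.221 at Plin4, 0.160 at Nlrp10 and 0.130 at Otof, each the highest over its alternatives, whose lowest values were 1.09e-05, 0.00132, 5.61e-04, 7.28e-10 and 4.24e-05. Leaving out H3K4me3 48 h replicate 1 also ended the calls at Plin4 (0.171) and Otof (0.0735), and leaving out H3K4me3 0 h replicate 2 that at Abcb1b (0.159), whose call was lost under 6 of 13 alternatives.

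Of 14357 genes tested in both assays, 511 were higher in both, against 220 if the calls were independent (odds ratio 3.70, 95% interval 3.27 to 4.18; two-sided Fisher's exact test p = 8.24e-91), and 224 were lower in both, against 68.4 (odds ratio 6.26, 5.13 to 7.64; p = 5.42e-70). With library size as the only scaling the balance turned, with 309 genes higher in both (odds ratio 5.53) and 469 lower in both (4.36). Opposite calls were fewer than independent calls would give. There were 10 genes higher in RNA and lower in H3K4me3, against 69.1 (odds ratio 0.121), and 105 lower in RNA and higher in H3K4me3, against 218 (odds ratio 0.411). Single H3K4me3 libraries moved these values: without 0 h replicate 1, 0 h replicate 2, 48 h replicate 1 and 48 h replicate 2 in turn, the odds ratio for higher in both was 20.1, 3.61, 7.41 and 2.34 and that for lower in both 17.5, 7.06, 8.14 and 4.01. In the same order, 1, 6, 7 and 24 genes were higher in RNA and lower in H3K4me3, and 4, 69, 26 and 228 lower in RNA and higher in H3K4me3, the last with an odds ratio of 0.694. Leaving out RNA libraries gave 5 to 11 and 47 to 118 such genes. H3K4me3 was called higher at 22.2% of the 2301 genes that rose in RNA and lower at 9.84% of the 2277 that fell, and of 9779 genes not called in RNA 7.76% were higher and 2.01% lower. The median H3K4me3 log2 fold was 0.11 for genes that rose in RNA, 0.04 for genes not called and -0.01 for genes that fell.

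Across genes, log2 fold changes in RNA and H3K4me3 had a Spearman correlation of 0.261, and levels correlated at 0.774 at 0 h and 0.776 at 48 h; genes are not independent replicates. The genes called in the same direction numbered 735, but 206 without H3K4me3 0 h replicate 1 and 451 without H3K4me3 0 h replicate 2.

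**Figure D3:**
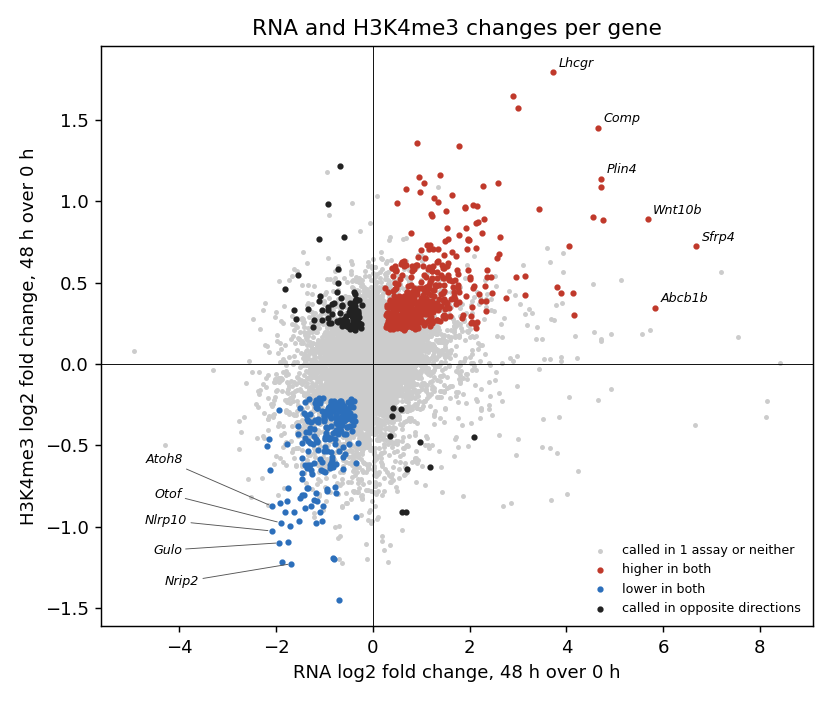
Log2 fold change (48 h over 0 h) in H3K4me3 against that in RNA for the 14357 genes tested in both, with genes higher in both in red, lower in both in blue, called in opposite directions in black and all others in grey. The 511 red and 224 blue genes stand beside 10 black genes higher in RNA and 105 black genes lower in RNA.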

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

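The tests chosen only after the result was seen were the crossed block, the windows above background, the identical counts kept once and the other scalings of the gene lists. No call of a gene selected for naming or of a list reversed, but the balance of higher and lower calls did: the share of higher calls went from 75.4% to 35.7% in H3K4me3 with a log2 fold minimum of 1 and from 50.2% to 26.8% in RNA with library size only, and genes higher and lower in both assays from 511 and 224 to 309 and 469 with library size only. Of the genes selected for naming, 95 of 118 in RNA and 68 of 122 in H3K4me3 kept their side of the threshold under every alternative run; by gene and alternative, 65 of 1416 comparisons lost and 7 gained a call in RNA, and 128 of 1562 lost and 17 gained one in H3K4me3. Of the list tests, 22 of 275 lost and 4 gained a call in RNA, and 19 of 225 lost and 7 gained one in H3K4me3. Among counts of calls and lists, 93 of 137 stayed within 1.5 times.

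The RNA count of 4585 fell to 1102 (637 higher, 465 lower) with a log2 fold minimum of 1 and to 2280 (1251 and 1029) at a threshold of 0.01, since fewer genes can pass either. With library size only, lower calls were 4222. The H3K4me3 count of 2062 became 70 (25 and 45) with the fold minimum, 1062 (783 and 279) at the stricter threshold and 865 (611 and 254) with DESeq2, which left 9016 adjusted p-values undefined. Library size only gave 945 higher and 862 lower, and windows above background only gave 900 lower. Under these settings the median of windows above background was -0.002 and 0.003, against 0.052 in the main fit. The balance of H3K4me3 calls thus moved with where the scaling put these windows. Which scaling is right was not tested, and the cause was not tested for RNA. Genes called in the same direction in both assays were 735, and 1227 at an unadjusted p in H3K4me3, a looser threshold.

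Without a replicate in turn, RNA counts ranged from 2882 (without 0 h replicate 3; 2956 without 0 h replicate 2) to 5345 and their lower calls from 1228 (without 48 h replicate 3; 1295 without 48 h replicate 2) to 2648. H3K4me3 counts ranged from 282 (without 0 h replicate 1; 1252 without 0 h replicate 2 and 1181 without 48 h replicate 1) to 2764, with 159 to 2070 higher and 123 to 694 lower, and genes in the same direction in both assays from 206 (without H3K4me3 0 h replicate 1; 451 without 0 h replicate 2) to 816. Where this left 1 H3K4me3 library in a group, that library was assumed to vary like the other group. Fewer libraries were fitted in each; why single libraries differ was not tested. Lists passing camera stayed between 11 and 16 in RNA and between 8 and 10 in H3K4me3.

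Library numbers did not pair the samples: RNA libraries of the same number deviated with correlations of -0.24, -0.12 and -0.22, and no library correlated best with its own number. With the number as a replicate block, 3312 RNA genes, 1280 H3K4me3 genes (908 higher) and 478 genes in the same direction were called. The block ended the RNA list call of gap junction genes (0.0785) and gave that of growing-follicle markers (0.0350). For H3K4me3, where the numbers come from the column names, the correlation was -0.375, and a crossed block called 4144 genes (3070 higher, 1074 lower).

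Camera with an estimated correlation called 0 of 25 lists in RNA and 0 in H3K4me3, against 14 and 8 at the preset value, with 5 and 4 lists at an unadjusted p under 0.05. In H3K4me3 the estimate was 0.0131 for FSH response genes and 0.0038 for growing-follicle markers, near or below the preset 0.01. With so few libraries that form of the test could hardly pass, so its losses do not show correlation among genes. Fry called 11 in RNA and 0 in H3K4me3 (12 at an unadjusted p under 0.05), and its mixed test 18 and 19. Not run were a pseudocount and a filter on low values, since the tables hold counts; transcripts one by one and the smallest p per gene, since each gene has 1 value; promoter regions only; and subtraction of input, which was not used here. In simulated data of the same depth, with changed genes of at least 5 CPM, edgeR recovered 86% of those changed by log2 1 in RNA. It recovered 91% of those changed by 0.5 in H3K4me3, so smaller changes, or changes at lower counts, can be missed.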

Other observations

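The tests chosen only after the result was seen were those of the granulosa share, of 48 h replicate 1 alone, of a larger response in it and of the minority cell type, and the grouping of genes by the start of their symbols. Several gene families had members moving together in RNA, and some share genes with the fixed lists, such as Nlrp14 in the Nlrp family. Zinc finger genes (Zfp) fell in 115 of 357 cases and rose in 1, with a median log2 fold of -0.28, and small nucleolar RNA host genes (Snhg) fell in 9 of 16 and rose in 0, with a median of -0.59. Transmembrane genes (Tmem) rose in 83 of 182 cases and fell in 7, and tetraspanins (Tspan) rose in 10 of 19 and fell in 0. Solute carriers (Slc) rose in 93 of 263 cases and fell in 25 (camera adjusted p = 0.00698). Protocadherins with the prefix Pcdh alone rose in 6 of 11 cases and fell in 0. Those named Pcdhb rose in 1 of 18 and those named Pcdhga in 3 of 12, and neither group passed (camera adjusted p = 0.125 and 0.132). Some other families of membrane proteins did not pass either, such as Gpr with 7 rises and 4 falls among 36 and Itga with 1 and 2 among 12. Of families with many oocyte-expressed members, Fbxw genes fell in 10 of 21 cases and Nlrp genes in 8 of 13, with medians of -1.29 and -1.41. They moved with the oocyte markers, of which 7 of 18 fell (median -1.03), and 48 h replicate 1 stood apart for all of these: relative to 0 h, the medians in 48 h replicates 1 to 3 were -0.40, -1.38 and -1.52 for Fbxw, -0.47, -1.60 and -2.17 for Nlrp and -0.18, -1.60 and -1.63 for the oocyte markers. The median log2 folds of Zfp, Snhg, Tmem, Tspan, Slc, Pcdh, Fbxw and Nlrp kept their signs under TMM, DESeq2 size factors and library size only. Their sizes moved: from TMM to library size only, Slc went from 0.21 to 0.04, Tmem from 0.34 to 0.17 and Zfp from -0.28 to -0.45. Camera called 20 of 170 families with at least 10 members (adjusted p = 6.66e-07 for Zfp and 3.21e-07 for Tmem), 0 with an estimated correlation (adjusted p = 0.880 for both; 4 at an unadjusted p under 0.05), and fry called 60.

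In H3K4me3, windows of vomeronasal (Vmn) and olfactory (Olfr) receptor genes, which granulosa cells are not known to use, had medians of -0.34 over 359 genes and -0.28 over 1120 genes, negative under all 3 scalings. Camera called them (1.12e-07 and 1.12e-05) among 26 of 268 families, and the adjusted p = 0.929 for both with an estimated correlation, where camera called 0 families (0 at an unadjusted p under 0.05) and fry 0 (33 unadjusted). Windows of genes with no RNA count had a median of -0.20, against 0.05 for windows above background, and of -0.25 against -0.00 with library size only. Their share of counts was 3.06% and 2.83% at 0 h and 2.72% and 3.04% at 48 h. Among single genes, Mir101c had 23988 and 15240 H3K4me3 counts at 0 h and 16430 and 67575 at 48 h, the last being 0.376% of its library. The glycolysis gene Eno1 had 1 RNA count over all libraries, and Hba-a1, Hba-a2, Hbb-bs and Hbb-bt had 0 in each.

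Of the 10 splits of the 6 RNA libraries into equal groups, 1, the real one, gave 4585 genes with edgeR (6256 at an unadjusted p under 0.05) and the highest other gave 0 (at most 1297 unadjusted). With 10 splits a share under 0.05 cannot be reached.

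Endothelial and red-cell markers rose in RNA at 48 h, although the samples are labelled as granulosa cells, and a second stromal list rose at 9 of 18 genes and fell at 0 (median 0.70; 1.30, 0.41 and 0.35 in 48 h replicates 1 to 3). A lower share of granulosa RNA would raise the markers of every other type alike. The median of surface epithelium markers was -0.16 (95% bootstrap interval -0.44 to 0.17), under the bound of 0.86. Only 1 of their 10 windows lay at background in H3K4me3, so the main cells may use these genes and the list decides little. Immune markers, with 13 of 15 windows at background, had a median of -0.13, and 0 of 14 passed. Both medians pool libraries of opposite sign. Relative to 0 h, surface epithelium was at 0.24 and immune at 0.23 in 48 h replicate 1, and both were below 0 in 48 h replicates 2 and 3. Bootstrap intervals here resample genes of a list, which move together, and do not cover the spread between libraries. The endothelial rise did not come from 48 h replicate 1 alone: without it the endothelial median was 0.98 (0.73 to 1.21) and 10 of 12 markers still passed. A higher share of several other cell types, stromal ones included, is not excluded. More endothelial RNA in the 48 h preparations stays open as a candidate explanation: a second list of 26 endothelial genes had a median of 1.54 (0.96 to 1.87) and rose at 17; 13 of these 26 genes had at least 5 CPM at 0 h, as had 7 of the 12 first markers, and 0 of either stand in another fixed list, with Cdh5, the most abundant first marker, at 29.8 CPM at 0 h and 107 CPM at 48 h. More red-cell RNA also stays open, with a median of 1.71 (0.16 to 2.16) over 11 further erythroid genes, of which 6 rose. Their medians from 0 h were 2.08, 0.36 and 1.32 in 48 h replicates 1 to 3. The globin genes, the most abundant in red cells, decide nothing here: they are at 0 in every library, but Eno1, a gene most cells use, is at 1 count in all, so such zeros may come from the counting. Growth of vessels around follicles after eCG and a different yield of vessel fragments at collection could both bring such RNA and were not told apart here.

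The 48 h replicate 1 stood apart from 48 h replicates 2 and 3: the oocyte markers had a median log2 difference from 0 h of -0.18 in it and of -1.60 and -1.63 in the others, and the matrix genes of 1.45, 0.34 and 0.47. A larger response to eCG in that library was not decided. In sets chosen without any RNA library, 431 genes called lower in H3K4me3 lay 0.24 higher in it than in the others (0.19 to 0.29 over genes). Their median from 0 h was -0.62 in the others, and 1375 genes called higher in H3K4me3 lay at -0.05 (-0.06 to -0.03). More RNA of other cells in that library could shift both sets this way, so they cannot exclude a larger response. Medians from 0 h in 48 h replicates 1 to 3 were 2.42, 1.65 and 2.00 for luteal markers and 1.63, 1.26 and 1.40 for cholesterol genes. They were 0.91, 0.80 and 0.71 for ovulatory genes, 0.99, 1.11 and 1.30 for steroidogenesis genes and 0.77, 0.83 and 0.80 for FSH response genes. More stromal and vascular RNA in that library stays open, since a second stromal list of 18 genes was 0.997 higher in it (0.89 to 1.19) and the second endothelial list 1.12 higher. It is not told apart from more RNA of other cells in general. Medians from 0 h in 48 h replicates 1 to 3 were 0.23, -0.47 and -0.03 for immune and 0.24, -0.34 and -0.35 for surface epithelium markers. At 0 h these lists also spread, from -0.36 to 0.38 and from -0.47 to 0.32. Theca markers were at 0.63, -0.29 and -0.22, but red-cell markers at 3.09, 0.79 and 3.10. Without 48 h replicate 1, 5345 genes were called in place of 4585, and Ccnd2 passed (adjusted p = 0.00273, in a range of 0.00273 to 0.258 over its alternatives).

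Some strongly expressed genes had H3K4me3 windows at background, such as Tenm4 (2669 CPM in RNA, 3.61 CPM in H3K4me3), Fat1, Nr5a2 and Cyp19a1 (518 and 1.23 CPM). RNA from a minority cell type may account for part of them: 35 of 64 expressed markers of other cell types (54.7%) had such a window, against 2 of 61 expressed genes of the granulosa lists (3.28%), an odds ratio of 34.6 (7.98 to 317; two-sided Fisher's exact test p = 3.88e-11). Among all expressed genes the share was 525 of 11286 (4.65%). The sets were not matched for RNA level, which correlated with the H3K4me3 count at 0.774 at 0 h. The odds ratio therefore does not bear on strongly expressed genes such as Tenm4. For Nr5a2 and Cyp19a1, which granulosa cells express, a promoter outside the counted window stays possible and was not tested, since the window is not given in the sources used here.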
